A study of Drosophila melanogaster with 12 samples.

How the data were processed

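RNA from whole embryos expressing 1 of 3 constructs under simGal4 was hybridised against RNA from embryos expressing GFP, with 4 two-colour arrays per construct, 12 in all. Per the file headers, each array file gives the median pixel intensity per spot, foreground and local background, in Cy3 and Cy5, without normalization, as quantified by Dapple. The series value table holds log2 ratios per spot made by the authors, construct over GFP. The submitters' processing notes name limma for the series without a version, and the method of normalization is not stated. Column medians of the deposited log2 table lie between -0.034 and 0.019, so each array was centred by the authors near 0. Its direction was checked against the dyes in the labels, since its correlation with the raw Cy5 over Cy3 ratio of bright spots runs from -0.999 to 0.999 with the sign that the labelled dye of the construct requires. On EnRep replicate 3 that correlation is only 0.549. The background correction and the normalization behind the deposited log2 values stay unknown.

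Intensities were processed in R 4.3.3 with limma 3.58.1. Each array carries 18240 spots, of which 14569 are in the value table and were used. The other 3671 were not analysed here. Background was corrected by normexp with an offset of 50, each array was normalised by global loess, the sign was set to construct over GFP, and spots of the same probe were averaged, 42 probes being printed more than once. This left 14485 probes. Of these, 12574 carry 1 gene symbol, 96 carry several and 1815 carry none, for 11980 genes. Probes without a symbol are given by the platform's reporter number. A RefSeq gene table of the Release 6 plus ISO1 MT assembly served only for gene names and for which genes neighbour each other, and 11928 probes matched it by gene identifier.

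A linear model in limma gave each construct its mean log2 ratio over GFP, with 1 term for dye orientation shared by all arrays, and empirical Bayes variances. The model has 8 residual degrees of freedom and 4.6 prior degrees of freedom. Dye effects were called for 4792 probes. Over all probes, called or not, the median size of the dye term was 0.11 log2, against a median residual SD of 0.19. The term was coded +1 and -1, so the gap between the 2 orientations is 2 times the term. Each construct has 2 arrays per dye orientation, and no array shares a slide with another. No other batch is given that holds more than 1 array. Comparisons were each construct over GFP and the 3 differences between constructs. P-values were two-sided and adjusted by Benjamini and Hochberg over all probes of a comparison, with 0.05 as the threshold. Folds are 2 to the power of the log2 ratio.

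Of 32 gene lists with 308 genes, 223 genes had a named probe, and 31 lists with at least 3 members were tested. The list of transgene markers had 0 members on the array. Camera, a competitive test, used a preset inter-gene correlation of 0.01 and was run again with an estimated correlation. With the estimated correlation 1 of the 17 list calls held, that of maternal transcripts in HMG-minus minus DichaeteWT. Fry, a self-contained test, was run beside it. P-values of lists were adjusted over the 31 lists of a comparison, and single members were also adjusted over the list alone.

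Named probes were, for each construct, the 10 called probes with the largest change in each direction that had the same sign on all 4 arrays, and for each contrast the 5 in each direction, filled with the smallest p where fewer passed. Added to these were D, sim, en, w, sli, comm, ac, l(1)sc, SoxN and vvl, and for each list up to 4 members with the smallest p. These groups, lists, rules and most alternatives were set before the data were examined. Genes described because they were called in all 3 constructs were chosen after their values were seen. Not every named probe's result is reported here.

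The model was tested on simulated data of the same size with 100 probes per construct changed by 0.5 log2 and another 100 by 1 log2. It recovered 62%, 63% and 58% of changes of 0.5 log2 and 95%, 97% and 96% of changes of 1 log2 for EnRep, DichaeteWT and HMG-minus, with 5 of 162, 8 of 168 and 9 of 163 calls false. The simulated noise was independent between probes and arrays, so these shares hold only for such noise. Real residuals correlated between arrays, at 0.67 for EnRep replicate 4 and DichaeteWT replicate 2. Alternatives changed the background correction, offset, normalization, probe filter, dye term, arrays used, replicate block, array weights and variance prior, used the deposited ratios, and left out each array in turn. Added after seeing the data were a covariate of late-gene level, spots accepted in both channels, print-tip loess together with a trended and robust variance, contrasts within a dye orientation, and list tests with print-tip loess or the deposited ratios. The share of spots accepted by the spot finder was 86.8% to 98.3% in Cy3 and 71.9% to 92.9% in Cy5.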

Results

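Total RNA from whole Drosophila melanogaster embryos of stage 8 to 9, collected 3.5 to 4.5 h after laying at 25 °C, was measured on two-colour arrays. The series concerns the role of Dichaete, a SoxB transcription factor with an HMG DNA-binding domain, in the ventral midline of the nervous system. The simGal4 driver, active in midline cells, expressed EnRep, DichaeteWT or HMG-minus, the names the labels give to 3 constructs. The design text calls the constructs dominant negative. The titles of the DichaeteWT arrays read UAS Dichaete WT, taken here as the wild type form, so that term was not applied to it. Each construct was compared on 4 arrays, 1 per biological replicate, with embryos in which the same driver expressed GFP. The construct was labelled with Cy3 on replicates 1 and 2 and with Cy5 on replicates 3 and 4. Median foreground intensity per array was 247 to 433 in Cy3 and 280 to 421 in Cy5, against median local backgrounds of 71 to 130 and 112 to 196. The number of arrays limits the precision. The median SE of a log2 ratio was 0.10 for a construct over GFP and 0.14 for a difference between constructs.

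The first question was whether transcripts of D, the gene that encodes Dichaete, differed from the GFP embryos. D rose in DichaeteWT embryos by 0.47 log2 (SE 0.08, 95% interval 0.30 to 0.64, n = 4, 1.38-fold, limma adjusted p = 0.0208). Whether the probe measured transcripts of the gene itself, of the transgene or of both could not be settled from the files. The 4 DichaeteWT arrays did not share a direction, with log2 ratios of 0.97 and 1.09 where the construct was in Cy3 and -0.06 and -0.14 where it was in Cy5. In EnRep embryos D was 0.37 log2 above GFP (SE 0.08, limma adjusted p = 0.0553), which did not pass, with 0.68, 0.71, 0.08 and 0.01 on replicates 1 to 4. In HMG-minus embryos the log2 ratio was 0.19 (SE 0.08, limma adjusted p = 0.317), with 0.58, 0.71, -0.28 and -0.24. None of the 3 differences between constructs passed for D, the largest being -0.27 for HMG-minus minus DichaeteWT (limma adjusted p = 0.903). The DichaeteWT call ended without DichaeteWT replicate 1 (adjusted p = 0.129), 2 (0.132) or 3 (0.0571), with replicate number as a block (0.0549), with median centring in place of loess (0.34 log2, 0.114), without a dye term (0.621), on its own 4 arrays alone (0.0746) and with a trended and robust variance (0.1), over a range of 0.00786 to 0.621. For EnRep the value fell below the threshold without DichaeteWT replicate 3 (0.0447) and under 5 other alternatives, and was 0.12 log2 with median centring and 0.20 with the deposited ratios.

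Genes of the midline itself showed no shift that passed. The list of midline primordium and midline glia genes, with 14 members measured, had median log2 ratios of -0.03, 0.10 and 0.00 in EnRep, DichaeteWT and HMG-minus embryos (camera adjusted p = 0.88, 0.536 and 0.805). In that list sli, which encodes the midline repellent Slit, had 0.21, 0.10 and 0.14, and comm, a regulator of midline crossing, had -0.27, -0.29 and -0.21. Median ratios of 11 midline neuron genes were -0.02, 0.01 and -0.01 (camera adjusted p = 0.828, 0.915 and 0.894). Among 17 proneural and neuroblast genes the medians were 0.01, -0.01 and -0.01, with ac at -0.29, -0.23 and -0.06 and l(1)sc at 0.00, -0.01 and 0.05. No member of these 3 lists was called by limma in any construct over all probes, and adjusted over the list alone 1 proneural and neuroblast gene was lower in EnRep and 1 in DichaeteWT. The median of the midline primordium and glia list in EnRep was below 0 while its mean, 0.01, and its test pointed up. The list of SoxB and neuroectoderm column genes had 1 called member of 9, D in DichaeteWT. Its SoxN, a second SoxB gene, had 0.03, -0.30 and -0.12, and vvl had 0.22, 0.38 and 0.18, none of them called. The segment polarity gene en had -0.13, 0.03 and -0.21, also not called. Some alternatives turned the sign of en in EnRep and DichaeteWT, SoxN in EnRep, l(1)sc in all 3 constructs, and ac in HMG-minus. Neither sim nor w had a probe among those tested, so the driver's own gene was not analysed here.

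EnRep over GFP asks which transcripts differ when EnRep is expressed in midline cells. The gene ppk20, which encodes a channel subunit of the pickpocket (DEG/ENaC) family, rose most, by 2.33 log2 (SE 0.13, n = 4, 5.02-fold, limma adjusted p = 2.48e-06), with 2.79, 2.86, 1.90 and 1.77 on the 4 arrays. RFeSP, the Rieske iron-sulphur protein of mitochondrial complex III, rose by 1.69 log2 (SE 0.12, 3.24-fold, adjusted p = 3.2e-05). Fadd, an adaptor of the Imd immune pathway, rose by 1.20 log2 (SE 0.11, adjusted p = 0.00022). Its GFP spot was accepted on only 2 of 4 arrays, so the size of that rise is uncertain, with 0.80 log2 without background correction and 1.80 with the smaller offset. The unnamed reporter 1000044200 rose by 1.73 log2 (SE 0.16, adjusted p = 0.000224). HnRNP-K, an RNA-binding protein of the hnRNP family, was lower than in GFP embryos on both of its probes. Their log2 ratios were -1.07 (SE 0.10, adjusted p = 0.000224) and -0.83 (SE 0.09, adjusted p = 0.00062). The first probe had -1.17 and -1.18 in DichaeteWT and HMG-minus embryos, so this difference was not particular to EnRep. Cyp4p2, a cytochrome P450, fell by 1.07 log2, CG13454 by 1.03, CG14453 by 0.91 and CG13991 by 0.82, each lower on 4 of 4 arrays.

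Of the histone genes, 5 of 8 rose in EnRep embryos. Their median log2 ratio was 0.70 over 8 members, of which 5 were called higher over all probes and 6 adjusted over the list alone, none lower (camera adjusted p = 2.74e-08 with the preset correlation). That call was lost at adjusted p = 0.168 with an estimated correlation, and fry, a self-contained test of whether the list's genes moved one way on balance, gave adjusted p = 0.00625. Examples were His2B:CG17949 at 0.84 log2 (SE 0.12), His3:CG31613 at 0.82 (SE 0.12), His4:CG31611 at 0.77 (SE 0.11) and His1:CG31617 at 0.75 (SE 0.11), the replication-dependent histones of near-identical repeated copies. The histone median was 0.22 and 0.33 on the arrays with EnRep in Cy3 and 1.23 and 0.96 on those in Cy5. The single-gene calls of His2B:CG17949, His3:CG31613 and His1:CG31617 ended without EnRep replicate 2 (adjusted p = 0.0623, 0.0689 and 0.0623) or 3 (0.0799, 0.0955 and 0.0936), and that of His4:CG31611 ended without replicate 3 (0.0613). With median centring the calls of His2B:CG17949 (0.52 log2, adjusted p = 0.0661), His3:CG31613 (0.50, 0.0689) and His4:CG31611 (0.42, 0.11) ended and that of His1:CG31617 held at 0.44 (0.0449). All 4 of these calls ended with a trended and robust variance and on the EnRep arrays alone, and all but that of His2B:CG17949 without a dye term. Genes of the dorsal ectoderm and amnioserosa, which form the dorsal side of the embryo, fell slightly as a list. Their median was -0.11 log2, with 0 of 13 members above 0 and none called (camera adjusted p = 0.0194, adjusted p = 0.168 with an estimated correlation, fry adjusted p = 0.0269). Among its members egr, the fly TNF ligand, had -0.26 (SE 0.08) and the T-box gene Doc2 -0.22 (SE 0.08). The list call ended without EnRep replicate 4 (adjusted p = 0.192) and without replicate 3, without the dimmest probes (0.058) and with the late-gene median as a covariate (0.0608). On EnRep replicate 4 the later muscle and cuticle genes had a median log2 ratio of 1.12, against -0.51, -0.23 and -0.25 on the other EnRep arrays.

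Over all 14485 probes, 62 were higher and 47 lower in EnRep embryos (limma, adjusted p below 0.05), for 35 and 40 named genes. Of these 109 probes, 101 had the same sign on all 4 arrays, against 16.5% of all probes. Calls were made on these same arrays, which favours equal signs, so that contrast does not measure reproducibility. The median size of a called change was 0.56 log2. Of 36 called EnRep results followed singly, 13 kept their call without any 1 array, among them ppk20, RFeSP, Fadd, HnRNP-K, Cyp4p2, CG13454, CG14453 and CG13991. The count was 49, 21 and 22 without EnRep replicate 1, 2 and 3, 70 without DichaeteWT replicate 1, 202 without DichaeteWT replicate 3, 61 without HMG-minus replicate 4, and 53 with replicate number as a block. It was 9 with a trended and robust variance, among them ppk20, RFeSP, Fadd and CG13454, while HnRNP-K, Cyp4p2, CG14453 and CG13991 lost their calls there. Median centring gave 34 higher and 85 lower, and the deposited ratios 38 higher and 57 lower, so the balance of directions depended on the scaling.

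**Figure D1:**
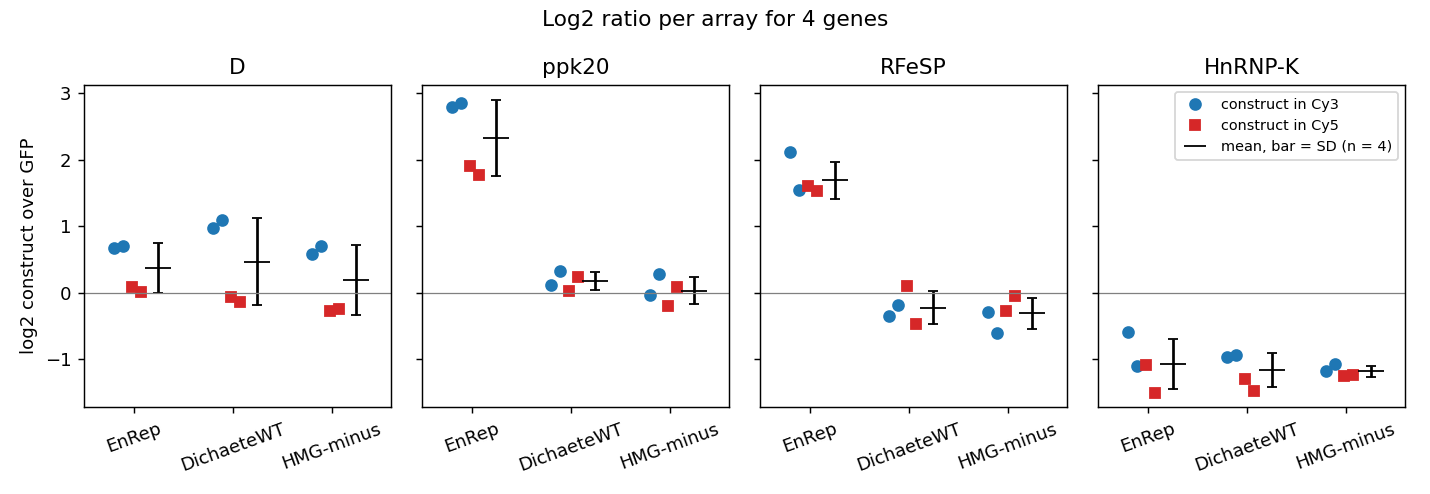
Log2 ratio of construct over GFP (vertical axis) on each of the 12 arrays for D, ppk20, RFeSP and a probe of HnRNP-K, by construct (horizontal axis). Points are arrays, coloured by the dye of the construct, and the black lines are the mean and SD of 4 arrays, with the 4 EnRep arrays between 1.77 and 2.86 for ppk20.

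DichaeteWT over GFP asks which transcripts differ when DichaeteWT is expressed in midline cells. Tektin-C, a structural protein of ciliary microtubules, rose by 0.70 log2 (SE 0.08, n = 4, 1.62-fold, limma adjusted p = 0.00102), on 4 of 4 arrays. The unnamed reporter 1000037757 was called higher (adjusted p = 0.000218), but its spot was accepted on only 1 of 4 arrays in either channel, so no size is given. Further rises were those of Faa, the last enzyme of tyrosine breakdown, by 0.71 log2 (SE 0.13, adjusted p = 0.0315), and of Fadd (adjusted p = 0.013), whose GFP spot was accepted on only 2 of 4 arrays and whose log2 ratio ran from 0.51 to 0.96 over the alternatives. The largest fall was that of CG12546, with a log2 ratio of -2.07 (SE 0.24, adjusted p = 0.00168). Cyp4p2 fell by 1.32 log2 (SE 0.13), EAChm by 1.28 (SE 0.15), HnRNP-K by 1.17 (SE 0.10) and 0.87 (SE 0.09) on its probes, and CG13991 by 0.81, each on 4 of 4 arrays. CG14453 was called lower too, with its construct spot accepted on only 2 of 4 arrays. In the dorsal ectoderm list, whose median was -0.10 with 1 of 13 members above 0 (camera adjusted p = 0.536), that member was tld, a protease of the Dpp pathway, which rose by 0.56 log2 (SE 0.08, adjusted p = 0.0103), and in the EGFR list kek1, a feedback inhibitor of the EGF receptor, fell by 0.43 (SE 0.09, adjusted p = 0.0427).

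Histone genes had a median of 0.38 log2 in DichaeteWT embryos, with 8 of 8 members above 0, 2 called over all probes and 5 adjusted over the list alone (camera adjusted p = 6.3e-05, adjusted p = 0.793 with an estimated correlation). The called members were His1:CG31617 at 0.59 (SE 0.11) and His3:CG31613 at 0.58 (SE 0.12). With median centring the histone call ended (adjusted p = 0.0686), and fry gave adjusted p = 0.0836. Genes of mitochondrial oxidative phosphorylation rose as a list by a median of 0.11 log2, with 53 of 69 members above 0 and 0 called by limma over all probes or adjusted over the list alone (camera adjusted p = 0.000889, adjusted p = 0.793 with an estimated correlation, fry adjusted p = 0.315). The members with the smallest p included ND-PDSW, of complex I, at 0.42 (SE 0.11) and COX5B, of complex IV, at 0.35 (SE 0.09), and also ND-15, of complex I, at -0.31 (SE 0.09). That call ended with median centring (adjusted p = 0.328) and without DichaeteWT replicate 3 (0.0523). The single-gene calls of both histones ended without DichaeteWT replicate 1 (adjusted p = 0.191 for His1:CG31617 and 0.238 for His3:CG31613), 2 (0.138 and 0.125) or 4 (0.0981 and 0.12), EnRep replicate 1 (0.0507 and 0.0657) or HMG-minus replicate 3 (0.0548 and 0.076) or 4 (0.0597 and 0.082), and that of His3:CG31613 also without DichaeteWT replicate 3 (0.111) or EnRep replicate 2 (0.0758) or 3 (0.0613).

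Over all probes, 55 were higher and 70 lower in DichaeteWT embryos, for 36 and 62 named genes. Of these 125 probes, 114 had the same sign on all 4 arrays, against 14.3% of all probes, a contrast that calling on these same arrays favours. Of 36 called DichaeteWT results followed singly, 13 kept their call without any 1 array, among them Tektin-C, CG12546, Cyp4p2, EAChm, HnRNP-K, CG14453 and CG13991. Of these genes, all but Tektin-C lost their call with a trended and robust variance, where 4 of the 36 kept theirs. The calls of Faa and kek1 ended without DichaeteWT replicate 1 (adjusted p = 0.171 and 0.181), 2 (0.144 and 0.156) or 3 (0.123 and 0.108) or HMG-minus replicate 3 (0.0548 and 0.0705) or 4 (0.0596 and 0.0758). The call of kek1 also ended without DichaeteWT replicate 4 (0.104), EnRep replicate 1 (0.0661), 2 (0.0589) or 3 (0.0578) or HMG-minus replicate 1 (0.0569), that of Fadd without replicate 1 (0.0685) or 4 (0.0581), and that of tld without replicate 1 (0.0549), 2 (0.0593) or 3 (0.0547). The count was 25, 16, 32 and 41 without DichaeteWT replicate 1, 2, 3 and 4, 77 without EnRep replicate 1 or 3, 235 without EnRep replicate 4, and 45 and 41 without HMG-minus replicate 3 and 4. It was 39 with replicate number as a block, 6 with a trended and robust variance, 30 higher and 82 lower with median centring, and 19 higher and 46 lower with the deposited ratios.

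HMG-minus over GFP asks which transcripts differ when HMG-minus is expressed in midline cells. CG14897 rose on both probes, by 1.09 log2 (SE 0.15, n = 4, 2.13-fold, limma adjusted p = 0.00547) and 0.77 (SE 0.14, adjusted p = 0.0237). The unnamed reporter 1000044200 rose by 1.65 log2 (SE 0.16, adjusted p = 0.000319). Other rises were those of Hsp27, a small heat shock protein, by 0.80 log2 (SE 0.14, adjusted p = 0.0236), BigH1, the maternal linker histone of the early embryo, by 0.79 (SE 0.15, adjusted p = 0.0281), and zpg, a germline gap junction protein, by 0.78 (SE 0.15, adjusted p = 0.0333). The tubulin-binding stathmin gene stai rose by 0.79 log2 (SE 0.12, adjusted p = 0.00864). EAChm fell by 1.43 log2 (SE 0.15, adjusted p = 0.000514), Cyp4p2 by 1.41 (SE 0.13), HnRNP-K by 1.18 (SE 0.10) and 0.98 (SE 0.09), Cyp28d2, another cytochrome P450, by 1.09 (SE 0.14), and CG13794 by 1.07, each on 4 of 4 arrays. CG15345 was called lower as well, but its construct spot was accepted on only 1 of 4 arrays, so no size is given. The gene kek1 fell by 0.61 log2 (SE 0.09, adjusted p = 0.00754).

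Maternal transcripts that embryos normally clear early were higher as a list in HMG-minus embryos. Their median was 0.29 log2, with 8 of 9 members above 0, 1 called over all probes and 5 adjusted over the list alone (camera adjusted p = 0.000421, adjusted p = 0.0823 with an estimated correlation, fry adjusted p = 0.0143). The called member was osk, the posterior determinant of the germ line, at 0.72 (SE 0.14, adjusted p = 0.0385). The others named were swa, which localises bicoid RNA, at 0.81 (SE 0.23), smg, the regulator of maternal RNA decay, at 0.70 (SE 0.22), and plu at 0.35 (SE 0.12), none of them called over all probes. The list median was above 0 on each HMG-minus array, at 0.32, 0.24, 0.12 and 0.19. The list call held without any 1 array and under each scaling tried. By its definition the list also follows embryo age, and whether the HMG-minus collections were younger was not tested. Germ cell and pole plasm genes, which include osk, rose by a median of 0.19 log2 with 1 of 8 called (camera adjusted p = 0.0228, adjusted p = 0.468 with an estimated correlation, fry adjusted p = 0.122). That call ended without HMG-minus replicate 3 (adjusted p = 0.144) and with median centring (0.134), print-tip loess (0.0935), the deposited ratios (0.0758) or the dimmest probes left out (0.09).

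Genes of the dorsal ectoderm and amnioserosa fell as a list in HMG-minus embryos too, by a median of -0.15 log2, with 0 of 13 above 0 and none called (camera adjusted p = 0.0022, adjusted p = 0.0823 with an estimated correlation, fry adjusted p = 0.0143). The T-box genes Doc3 and Doc2 had -0.21 and -0.19, and the GATA factor pnr had -0.19, each with SE 0.08 or 0.09. Cytosolic ribosomal protein genes rose as a list by a median of 0.11 log2, with 34 of 39 above 0 and none called (camera adjusted p = 0.000215, adjusted p = 0.474 with an estimated correlation, fry adjusted p = 0.208). Adjusted over the list alone, 2 ribosomal protein genes were higher and 1 lower, and RpL22-like had 0.49 log2 (SE 0.10). The histone list had a median of 0.20 log2, with 7 of 8 above 0 and none called (camera adjusted p = 0.00903, adjusted p = 0.474 with an estimated correlation, fry adjusted p = 0.208). Median centring ended the ribosomal and histone calls (adjusted p = 0.239 and 0.235), as did leaving out HMG-minus replicate 1 for the ribosomal list (0.178) and replicate 2 for the histones (0.517).

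Over all probes, 61 were higher and 63 lower in HMG-minus embryos, for 45 and 48 named genes. Of these 124 probes, 117 had the same sign on all 4 arrays, against 16.1% of all probes, a contrast that calling on these same arrays favours. Of 37 called HMG-minus results followed singly, 14 kept their call without any 1 array, among them EAChm, Cyp4p2, HnRNP-K, CG13794 and the stronger CG14897 probe, though each of these ended with a trended and robust variance, where 1 of the 37 kept its call. The calls of Hsp27, BigH1, zpg, stai and osk ended without HMG-minus replicate 3 (adjusted p = 0.188, 0.228, 0.241, 0.087 and 0.275) or 4 (0.196, 0.235, 0.258, 0.097 and 0.248). Those of Hsp27 and zpg also ended without replicate 1 (0.054 and 0.0503), those of Hsp27, BigH1, zpg and osk without replicate 2 (0.0536, 0.0536, 0.0536 and 0.15), those of osk and zpg without EnRep replicate 2 (0.0571 for both) or 3 (0.0597 and 0.0526) or DichaeteWT replicate 4 (0.0544 and 0.0527), and that of osk without EnRep replicate 1 (0.0622). The call of kek1 ended without HMG-minus replicate 1 (0.0503), 3 (0.085) or 4 (0.0955), that of Cyp28d2 without replicate 4 (0.0526), and that of the weaker CG14897 probe without replicate 1 (0.0573), 2 (0.13), 3 (0.0798) or 4 (0.172). The count was 43, 48, 25 and 17 without HMG-minus replicate 1, 2, 3 and 4, 238 without EnRep replicate 4, 191 without DichaeteWT replicate 3, 62 with replicate number as a block, 76 with median centring and 9 with a trended and robust variance.

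**Figure D2:**
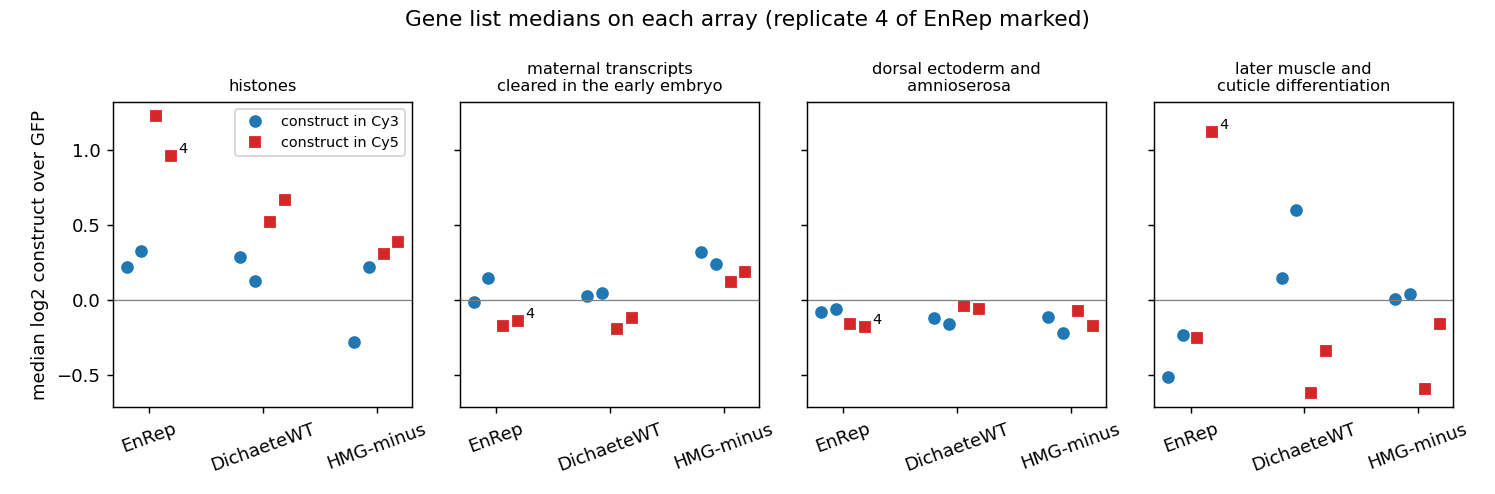
Median log2 ratio of construct over GFP (vertical axis) over the measured members of gene lists on each of the 12 arrays, grouped by construct (horizontal axis), with points coloured by the dye of the construct. The histone median on the EnRep arrays lies between 0.22 and 1.23, and the later muscle and cuticle median on EnRep replicate 4 is 1.12.

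The direct comparison of the constructs asks where transcript levels differ between their embryos. It cannot tell an effect of a construct from other differences between the lines that carry them. EnRep exceeded DichaeteWT in ppk20 by 2.15 log2 (SE 0.18, 4.45-fold, limma adjusted p = 0.000399) and in RFeSP by 1.92 (SE 0.17, 3.79-fold, adjusted p = 0.000429). EnRep exceeded HMG-minus in ppk20 by 2.29 log2 (SE 0.18, adjusted p = 0.000192), in RFeSP by 2.00 (SE 0.17, adjusted p = 0.000267) and in Fadd (adjusted p = 0.0402). The size of the Fadd difference is uncertain, with 0.63 to 1.57 log2 over the alternatives, and its call was lost in 19 of 27 of them. The unnamed reporter 1000039807 was lower in EnRep than in DichaeteWT at -1.18 log2 (adjusted p = 0.00957), and reporter 1000035949 lower in EnRep than in HMG-minus at -0.92 (adjusted p = 0.0402). These were all 3 and 4 of the probes called in the respective contrasts, with 648 and 992 at an unadjusted p under 0.05. With a trended and robust variance 1 of the 3 and 2 of the 4 kept their calls. Between HMG-minus and DichaeteWT limma called 0 probes, with 764 at an unadjusted p under 0.05, and it called 0 or 2 probes without any 1 array, 2 being the count without EnRep replicate 4. Among named genes there, Obp57a, an odorant-binding protein, had the smallest adjusted p, with -0.82 log2 (SE 0.13, adjusted p = 0.146). On simulated data with independent noise and 100 probes changed at each of these sizes, 81% to 91% of differences of 1 log2 between constructs were recovered and 21% to 31% of those of 0.5 log2. The EnRep minus HMG-minus count was 2 without EnRep replicate 2, DichaeteWT replicate 1 or 3, or HMG-minus replicate 1, 3 or 4, and 14 without HMG-minus replicate 2. In EnRep minus HMG-minus the calls of Fadd and reporter 1000035949 each ended in those same runs that gave 2 and also without EnRep replicate 1 (0.176 for both) or HMG-minus replicate 2 (0.0629 for both). That of Fadd ended too without EnRep replicate 3 (0.152), with 0.23 the highest, and that of reporter 1000035949 without EnRep replicate 4 (0.123) or DichaeteWT replicate 4 (0.082), with 0.223 the highest. In EnRep minus DichaeteWT the call of reporter 1000039807 ended without EnRep replicate 1 (0.0637), 2 (0.0629) or 3 (0.0583). On the arrays with the construct in Cy3 alone the 3 contrasts gave 378, 163 and 10 probes for EnRep minus DichaeteWT, HMG-minus minus DichaeteWT and EnRep minus HMG-minus, and on those in Cy5 alone limma called 0 in each, with 990, 718 and 990 at an unadjusted p under 0.05.

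Maternal transcripts differed as a list between HMG-minus and both other constructs, with a difference in embryo age not tested. HMG-minus exceeded DichaeteWT by a median of 0.30 log2, with 8 of 9 members above 0 and none called singly (camera adjusted p = 8.42e-05, adjusted p = 0.0483 with an estimated correlation, fry adjusted p = 0.0552). EnRep lay below HMG-minus by a median of -0.35 log2, with 1 of 9 above 0 and 4 lower adjusted over the list alone (camera adjusted p = 0.000131, adjusted p = 0.066 with an estimated correlation, fry adjusted p = 0.0612). Histones were higher in EnRep than in HMG-minus by a median of 0.50 log2 (camera adjusted p = 0.000323, adjusted p = 0.662 with an estimated correlation), a call that ended with median centring (0.113). Ribosomal protein genes were lower in EnRep than in DichaeteWT and HMG-minus, with medians of -0.09 and -0.14 (camera adjusted p = 0.00308 and 7.86e-05, adjusted p = 0.922 and 0.662 with an estimated correlation). Oxidative phosphorylation genes were lower in EnRep than in both, with medians of -0.12 and -0.07 (camera adjusted p = 6.52e-06 and 0.0118, adjusted p = 0.922 and 0.677 with an estimated correlation). Notch and E(spl) complex genes, targets and regulators of Notch signalling, were lower in EnRep than in DichaeteWT by a median of -0.21, with 2 of 13 above 0 (camera adjusted p = 0.00308, adjusted p = 0.922 with an estimated correlation). No member of the ribosomal, oxidative phosphorylation or Notch lists was called singly by limma in these contrasts. RFeSP, a complex III protein that the oxidative phosphorylation list does not hold, went the other way, at 1.92 and 2.00 log2. Tested for moves one way, fry passed for no list in EnRep minus DichaeteWT or in EnRep minus HMG-minus. Its mixed form, which takes moves in either direction, passed for maternal transcripts in EnRep minus HMG-minus (fry mixed adjusted p = 0.0138). The Notch call ended without EnRep replicate 4 (adjusted p = 0.622) or DichaeteWT replicate 3, the ribosomal call against DichaeteWT without DichaeteWT replicate 3 (0.428) or EnRep replicate 3 and with print-tip loess (0.0586), and the oxidative phosphorylation call against HMG-minus without EnRep replicate 3 (0.508), EnRep replicate 2 or HMG-minus replicate 4.

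Many probes moved the same way in more than 1 construct. Of 269 probes called in at least 1 construct, 43 were called in 2 and 23 in all 3, each in the same direction, and none was called in opposite directions in any pair. The 23 probes were 6 higher and 17 lower. HnRNP-K, Cyp4p2 and EAChm were lower on 12 of 12 arrays, with log2 ratios of -1.07, -1.32 and -1.41 in EnRep, DichaeteWT and HMG-minus embryos for Cyp4p2, and EAChm lower by 2.01-, 2.42- and 2.69-fold. CG13991 had -0.82, -0.81 and -0.83. Each ratio is taken over GFP embryos, so near-equal falls can also come from a higher level on the GFP side. The calls of HnRNP-K, Cyp4p2, CG13991 and CG14453 held in each construct without any 1 array. CG14897 was higher on 12 of 12 arrays at 0.89, 0.79 and 1.09. Its EnRep call ended without EnRep replicate 2 (adjusted p = 0.16) or 3 (0.161), and its DichaeteWT call without DichaeteWT replicate 1 (0.0882), 2 (0.149), 3 (0.13) or 4 (0.0621) or HMG-minus replicate 3 (0.0574) or 4 (0.0597). The EnRep call of EAChm ended without EnRep replicate 1 (0.0539), 2 (0.0805) or 3 (0.0826). For EnRep and DichaeteWT 12 probes were higher in both and 24 lower in both. For EnRep and HMG-minus these were 14 and 21, and for DichaeteWT and HMG-minus 12 and 29. Independent calls would give 0.20 to 0.30 of each kind. The calls were not independent, since the 3 constructs shared 1 spread estimate and 1 dye term per probe. That contrast therefore does not measure agreement between constructs. Across probes, which are not independent replicates, the log2 ratios correlated at Pearson r = 0.52, 0.41 and 0.45 (Spearman rho 0.48, 0.34 and 0.40). In simulated data in which constructs shared the GFP sample by replicate number and nothing changed, r was 0.50 and at most 0.05 probes were called in both on average. Taken from arrays of different replicate numbers, r was 0.37, 0.21 and 0.34. The count in all 3 constructs was 14, 8 and 10 without EnRep replicate 1, 2 and 3, 12, 8 and 14 without DichaeteWT replicate 1, 2 and 4, and 15, 9 and 9 without HMG-minus replicate 1, 3 and 4. It was 13 with replicate number as a block, 0 with each construct fitted on its own arrays and 0 with a trended and robust variance.

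**Figure D3:**
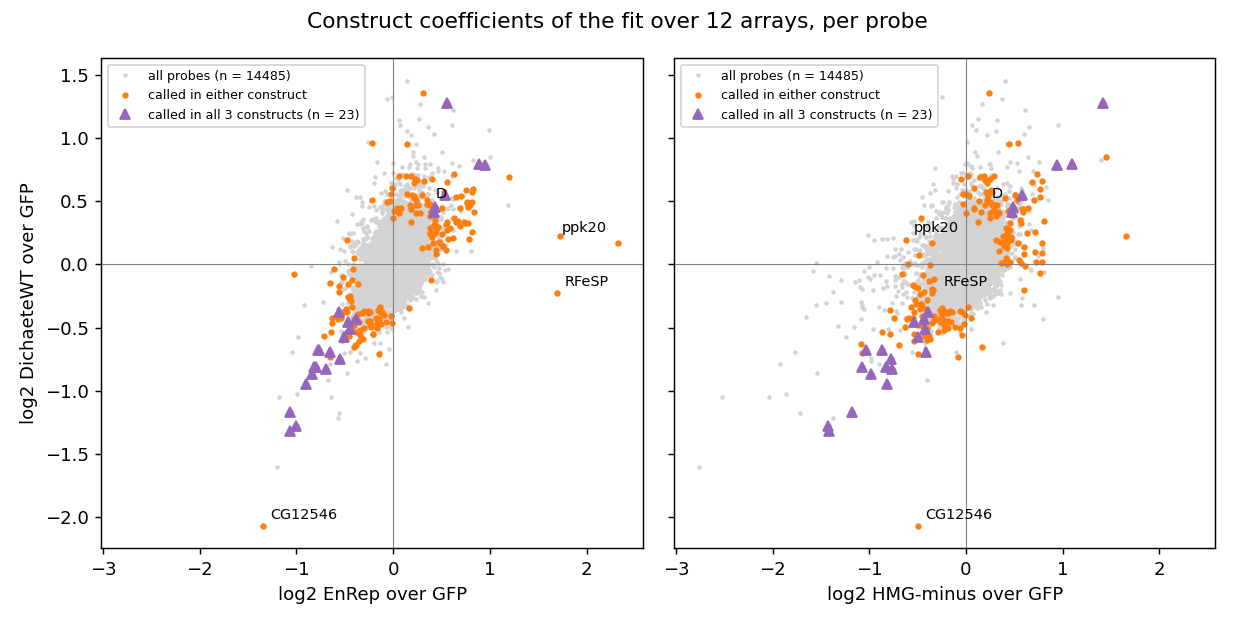
Fitted log2 ratio over GFP of 14485 probes in DichaeteWT embryos (vertical axes) against EnRep (left) and HMG-minus (right) embryos. Grey points are all probes, orange points those called in either construct of the panel, and purple triangles the 23 probes called in all 3 constructs, each on the same side of 0 on both axes.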

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

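The tests of a mislabelled array and of neighbouring genes, and the covariate of late-gene level, were chosen only after the result was seen. A gap between an array and its group's nearest array, large against the group's range, marked 7 of 186 groups of 4 arrays, where chance marks about 1 in 20, or 9.3. The share of the range taken by the gap was 0.87 for RFeSP in EnRep, with replicate 1 at 2.11 and the others at 1.53 to 1.60. It was 0.853 for CG12546 in EnRep, with replicate 4 at -0.21 and the others at -1.83 to -1.59. For Cyp4p2 in HMG-minus it was 0.848, with replicate 2 at -0.80 and the others at -1.70 to -1.56. Among list medians it was 0.871 for EGFR signalling in EnRep (replicate 3 at -0.04, the others -0.20 to -0.18) and 0.879 for segment polarity and pair-rule genes in DichaeteWT (replicate 3 at 0.24, the others -0.05 to -0.02). It was 0.943 for haemocyte genes in EnRep (replicate 1 at 0.04, the others -0.11 to -0.10) and 0.859 for ribosomal protein genes in EnRep (replicate 4 at 0.20, the others -0.11 to -0.07).

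Differences between constructs that passed limma were those of ppk20 (2.15 log2 in EnRep minus DichaeteWT and 2.29 in EnRep minus HMG-minus), RFeSP (1.92 and 2.00), Fadd (1.05 in EnRep minus HMG-minus), reporter 1000039807 (-1.18 in EnRep minus DichaeteWT) and reporter 1000035949 (-0.92 in EnRep minus HMG-minus). Lists that differed by camera in EnRep minus DichaeteWT were Notch and E(spl) complex and ribosomal protein genes (adjusted p = 0.00308 each) and oxidative phosphorylation (6.52e-06). Each of these calls was lost at adjusted p = 0.922 with an estimated correlation. Maternal transcripts differed in HMG-minus minus DichaeteWT (8.42e-05) and EnRep minus HMG-minus (0.000131). With an estimated correlation the former held narrowly (adjusted p = 0.0483, fry 0.0552) and the latter was lost (adjusted p = 0.066). In EnRep minus HMG-minus ribosomal protein genes (7.86e-05), histones (0.000323) and oxidative phosphorylation genes (0.0118) differed too, calls that were lost at adjusted p = 0.662, 0.662 and 0.677 with an estimated correlation.

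Later muscle and cuticle genes stood apart on EnRep replicate 4, with a median of 1.12 log2 against -0.51 to -0.23 on the other EnRep arrays. Position on the slide was argued against, since the median stayed at 1.1 with print-tip loess. A mislabelled array was argued against by ppk20, the 1 gene tested, at 1.77 there and at most 0.32 on the arrays of other constructs. RFeSP lay apart in the same way, at 1.53 there and at most 0.10 on those arrays. Both genes came from calls that included this array. Over all probes EnRep replicate 4 had r of -0.028 with EnRep replicate 3, of the same dye orientation. That is the lowest of 6 pairs of the same construct and orientation, whose median was 0.55. With EnRep replicates 1 and 2, of the opposite orientation, r was -0.257 and -0.179, within the range of such pairs (-0.4 to -0.01). With DichaeteWT replicates 1 and 2, of the opposite dye orientation, r was 0.305 and 0.452. Older animals in that EnRep collection stay a possible explanation. The Osi family of cuticle genes, a test set for it, was higher there by 0.2 log2 (SE 0.21 over 24 members, 18 of them higher), which left it undecided. No biological explanation was tested.

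The other pattern weighed was that 66 probes were called in 2 or 3 constructs in the same direction. GFP RNA shared by arrays of the same number was argued against. The covariance between constructs from different numbers was 1.02 times that from the same numbers (SD 0.36 over 3 pairs). A single GFP pool behind all arrays stays open. Over all arrays of a dye, the median SD of the GFP channel was 0.22 log2 in Cy3 and 0.24 in Cy5. Construct channels had 0.23 and 0.29 within constructs. These SDs include noise between arrays, so they cannot decide it. Older animals in some collections were left undecided. With late-gene level as a covariate 66 of the 66 probes kept their calls. That covariate was centred over all arrays, so it could not remove a shift common to the constructs. A GFP line that differs from the construct lines over linked stretches of the genome may contribute, with 2 neighbouring pairs among 45 genes placed (mean of 10000 permutations 0.17, permutation p = 0.013), but both pairs lie in 1 run of 3 genes, CG12546, CG14453 and CG32453, so the test was read as undecided once that was seen. A GFP line that differs at unlinked genes, which the test of neighbours cannot show, also stays open. An effect of midline expression common to the constructs stays open too, untested.

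Other splits of the arrays were counted for each comparison. For a construct over GFP there are only 8 choices of channels, too few for a share under 0.05, and 1 choice gave as many probes in each. The counts were 109, 125 and 124 for EnRep, DichaeteWT and HMG-minus, and the highest other counts 32, 0 and 0. For EnRep minus HMG-minus, 1 of 35 splits, the real one, gave as many as the 4 probes, the highest other giving 1. That is the smallest share that 35 splits allow. It was reached in 1 of 3 contrasts, and many splits do not keep the balance of dyes, so chance was not excluded. For EnRep minus DichaeteWT chance was not excluded either, since 2 of 35 splits gave 3 or more. The split that set EnRep replicates 1 to 3 with DichaeteWT replicate 4 gave 215 probes, which points to a structure of the samples. For HMG-minus minus DichaeteWT 0 probes were called in the real split and at most 0 in the others, so 35 of 35 splits gave as many by construction, which says nothing about chance.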

How the results depend on the processing

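The late-gene covariate, accepted spots, contrasts within a dye, print-tip loess with a trended and robust variance, and list tests with print-tip loess or the deposited ratios were chosen after seeing the data. The cause was not tested for any change below, except that runs on fewer arrays have fewer samples. Of 3103 values of 116 called gene results under alternatives, 2401 kept direction and call, 702 kept direction only and 0 reversed. Of 2661 values of 96 gene results not called, 61 gained a call and 73 changed sign without one, and of 3205 values of 169 lists not called, 41 gained a call and 283 changed sign without one. Among these, comm in HMG-minus passed with array weights (-0.33 log2, adjusted p = 0.0423, over a range of 0.0423 to 0.831). Of 323 values of 17 called lists, 282 kept the call and 41 lost it. The later muscle and cuticle list in EnRep reversed without EnRep replicate 4, where it was lower (adjusted p = 0.0184, with 0.0184 to 0.929 over runs without 1 array). Median backgrounds of 71 to 196 under foregrounds of 247 to 433 limit ratios of dim probes, and 390 gene values could not be computed in an alternative. Residuals correlated above 0.1 in 2 of 12 pairs of arrays of the same replicate number (median -0.12, range -0.64 to 0.24). No general positive pairing by number was seen, but large values of either sign leave the question unsettled.

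In the order EnRep, DichaeteWT and HMG-minus over GFP, the counts of 109, 125 and 124 became 265, 465 and 381 with print-tip loess, 29, 25 and 23 without a dye term, 4, 63 and 248 on only the arrays compared, 349, 276 and 1098 with array weights, 9, 6 and 9 with a trended and robust variance, and 169, 367 and 294 with the late-gene covariate. With replicate number as a block they were 53, 39 and 62. DichaeteWT gave 65 with the deposited ratios, DichaeteWT and HMG-minus gave 230 and 213 with print-tip loess and a trended and robust variance, and HMG-minus gave 76 with median centring. The 23 probes called in all 3 became 51 with print-tip loess, 7 without a dye term, 0 on only the arrays compared, 13 with the block, 55 with array weights, 0 with a trended and robust variance, 40 with the covariate and 2 with print-tip loess and that variance.

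EnRep minus DichaeteWT, with 3, gave 5 with print-tip loess, 1 with a trended and robust variance, 5 with the covariate, 378 in Cy3 alone and 0 in Cy5 alone. HMG-minus minus DichaeteWT, with 0, gave 3 with print-tip loess, 2 with array weights, 6 with the covariate, 3 with print-tip loess and a trended and robust variance, and 163 in Cy3 alone. EnRep minus HMG-minus, with 4, gave 2 without background correction, 2 without a dye term, 2 on only the arrays compared, 2 with the block, 2 with a trended and robust variance, 8 with array weights, 10 in Cy3 alone and 0 in Cy5 alone. It gave 1 without the dimmest probes, 1 with accepted spots and 1 with print-tip loess and a trended and robust variance.

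D in EnRep passed at 0.36 without background correction (adjusted p = 0.0359), 0.37 without the dimmest probes (0.0437), 0.34 with array weights (0.0319), 0.35 with the covariate (0.0412) and 0.37 with accepted spots (0.0446), over a range of 0.0319 to 0.794. In DichaeteWT it lost its call at 0.34 with median centring (0.114) and at 0.47 without a dye term (0.621), on only the arrays compared (0.0746), with the block (0.0549) and with a trended and robust variance (0.1). Lists called numbered 2, 2, 5, 3, 1 and 4 in the 3 constructs and then EnRep minus DichaeteWT, HMG-minus minus DichaeteWT and EnRep minus HMG-minus. With an estimated correlation they numbered 0 in all but HMG-minus minus DichaeteWT, which kept 1. Without the dimmest probes EnRep had 1 and DichaeteWT 4, with median centring EnRep, DichaeteWT and HMG-minus had 5, 0 and 2, and with the deposited ratios EnRep had 5. With the covariate EnRep had 1 and HMG-minus minus DichaeteWT 2, as the latter did with print-tip loess.

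Leaving out 1 array at a time gave 21 to 202 probes for EnRep, 16 to 235 for DichaeteWT, 17 to 238 for HMG-minus, 2 to 4 for EnRep minus DichaeteWT, 0 to 2 for HMG-minus minus DichaeteWT, 2 to 14 for EnRep minus HMG-minus and 8 to 29 in all 3 constructs. The correlations ranged over 0.32 to 0.52, 0.26 to 0.46 and 0.35 to 0.51, and D over 0.31 to 0.42, 0.40 to 0.53 and 0.17 to 0.21 log2. Lists called ranged over 1 to 6, 1 to 5, 4 to 6, 1 to 4, 1 to 2 and 3 to 5.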

Other observations

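Haemocyte and Hox genes passed in HMG-minus embryos by fry, which asks whether a list's genes move one way on balance, and not by camera, which compares them with other genes. Haemocyte genes had a median of -0.16 log2 in HMG-minus embryos, with 1 of 7 above 0 (fry adjusted p = 0.0446, camera adjusted p = 0.0588, adjusted p = 0.353 with an estimated correlation). Hox genes had a median of -0.14 log2, with 1 of 4 above 0 (fry adjusted p = 0.0331, camera adjusted p = 0.139, adjusted p = 0.468 with an estimated correlation). Segment polarity and pair-rule genes had medians of -0.09, -0.02 and -0.07 in EnRep, DichaeteWT and HMG-minus embryos, and EGFR signalling genes -0.03, 0.08 and 0.04, with kek1 the called member in DichaeteWT and HMG-minus.

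The later muscle and cuticle median on DichaeteWT replicate 2 was 0.60.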
